A study of Mus musculus with 50 samples.

How the data were processed

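Gene-level read counts for 50 libraries were read from the gene table deposited with the series; per the submitters' processing notes, reads were aligned with STAR and assigned to genes with featureCounts. These values are read counts, whole numbers that were used without rescaling. A separate deposited table holds transcript-level values from kallisto, and these values are estimated counts, which were summed per gene for 1 alternative analysis and used nowhere else. The notes state no version for STAR, featureCounts, kallisto or edgeR, and the genome build, the gene annotation and the strand setting are not given in the sources used here. Sequencing is described as Illumina HiSeq on total RNA, and the reads themselves were not analysed here.

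The gene table has 39056 entries, of which 12061 had no count in any library. Without the version part of the identifiers, 38872 entries matched GENCODE M21 (GRCm38), which gave gene symbols and positions, and 184 did not; with the version part 34299 matched. The isoform table has 112588 transcripts, of which 111887 could be assigned to a gene of the gene table, and these hold 99.65% of the estimated counts. Every column of both tables belongs to a sample of the series.

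Genotype, treatment and hour of each library were taken from the sample labels. There are 20 groups: 10 wild-type groups with 2 libraries each and 10 Nrf2 -/- groups with 3 libraries each, untreated and IFN-γ at 1, 8, 24 and 48 h and thapsigargin at 1 and 8 h. In 3 libraries, replicate 2 of the Nrf2 -/- 8 h groups, the title and another field of the label name different genotypes; the title was followed in the main analysis. Replicates were numbered within each group in the order of the library numbers in the labels. The labels do not say that replicates are separate cultures, so all p-values here measure the spread between these libraries, which may be technical. Culture, animal and sequencing batch are not given in the sources used here, and no term for them was used.

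Genes were kept by filterByExpr on the 20 groups (at least 10 counts in the smallest group size, at least 15 in total), which left 16460 genes. Libraries were scaled by TMM, and 1 negative binomial model with a mean for each group was fitted to all 50 libraries with edgeR 4.0.16 (quasi-likelihood, robust). The common dispersion was 0.00983. Each of 24 comparisons is a contrast of group means: Nrf2 -/- minus wild type averaged over the hours of a treatment (3 comparisons), treated minus untreated at the same hour within a genotype (12), the difference between genotypes in each of these responses (6), and 48 h minus 1 h in untreated cells of each genotype with the difference between them (3). Adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, and a gene was called at an adjusted p below 0.05. Folds are log2 with a standard error (SE) from the model, and CPM are counts scaled by TMM library size, given as mean ± SD over the libraries of a group. The named comparisons, the model, the threshold, the gene lists and most alternatives were chosen before the data were examined; what was added later is named where it is used.

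For genes with 3 or fewer counts in the control group, fitted folds depend on a small added constant, so they are not printed. In their place a lower bound is given as "at least", with 3 counts over the group standing in for 0, or a ratio with a 95% interval. That interval comes from the exact Poisson limits of the control count, with the treated count held fixed. These intervals cover the counting error of the control group only.

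The 22 gene lists were written from general knowledge of the pathways and cell types before the data were examined. They cover, apart from 1 list not reported here, NRF2 targets; glutathione and thiol metabolism outside NRF2 targets; MHC class I and antigen processing; MHC class II; type I interferon-stimulated genes; NF-κB and chemokine genes; ATF4 and CHOP targets; ER chaperones and ATF6 targets; XBP1 and ERAD genes; p53 and cell-death genes; immediate early genes; cell cycle; cholesterol synthesis; mature oligodendrocyte and myelin; oligodendrocyte progenitor; astrocyte markers; microglia and macrophage markers; neuron markers; endothelial, mural and fibroblast markers; sex-linked transcripts and mitochondrially encoded transcripts. Each list was tested with camera (limma 3.58.1) against all other tested genes with a preset correlation of 0.01 between genes, adjusted over the 22 lists by Benjamini-Hochberg. A second run estimated the correlation from the data and is printed as "with an estimated correlation". For each list the text gives the members called over all genes and the number called when p-values were adjusted over the list alone.

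Genes named in the text follow a rule. In the genotype comparisons these are Nfe2l2 and 7 NRF2 targets fixed in advance (Nqo1, Hmox1, Gclc, Gclm, Txnrd1, Srxn1 and Slc7a11). In each comparison they are the 6 highest and the 6 lowest log2 folds among called genes with a mean of at least 5 CPM in the higher group and every library of one group above every library of the other. For comparisons averaged over hours the group means had to differ in the same direction at every hour, and for differences between responses no separation was asked for. Genes without a common name and pseudogenes were passed over. In each list up to 3 called members with the largest absolute fold could be named, or the member with the highest mean CPM if none was called. All called genes of the genotype comparisons in untreated and IFN-γ-treated cells are named as well, which was decided after their values were seen. A gene chosen in one comparison could be followed in another, and not every gene that met the rule is printed.

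The pipeline was also run on simulated counts with known answers, drawn from a negative binomial distribution with the gene means, gene dispersions and library sizes of the real table, with 200 genes changed by known folds, 50 per fold size. Of changed genes with at least 5 CPM, the edgeR model recovered 28 of 29 (96.6%) at 2-fold, 25 of 39 (64.1%) at 1.5-fold and 4 of 35 (11.4%) at 1.25-fold for the IFN-γ 24 h difference between genotypes (15817 genes tested). For the thapsigargin 8 h difference it recovered 25 of 29 (86.2%) at 2-fold (15830 genes). For the untreated genotype comparison it recovered 26 of 26 at 1.5-fold and 23 of 34 (67.6%) at 1.25-fold (15826 genes), and for IFN-γ at 24 h in wild type 29 of 30 (96.7%) at 2-fold (15829 genes). False calls were 3.9% to 6% of all calls with edgeR and 8.9% with DESeq2 in the 1 comparison it was run on (16460 genes). The simulated libraries were independent and held no shared culture, sex or other structure, so these rates may not hold for the real libraries. With 200 genes changed, the adjusted threshold was also less strict than in real comparisons with few or no calls.

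Alternatives chosen before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a model with only the libraries of the same time or treatment, the 3 libraries with conflicting labels left out or treated as wild type, kallisto estimated counts summed per gene, an added requirement of an absolute log2 fold of at least 1, camera with an estimated correlation, fry, and leaving out each library in turn. Alternatives added after the data were seen were leaving out 2 untreated 8 h libraries whose Nfe2l2 count lay against or midway to their label, a model term for libraries with at least 50 CPM of Xist, and both of these and the leave-one-out runs for the lists. Group labels were also exchanged in up to 100 other splits of the same libraries for the genotype comparisons and in all 10 splits for comparisons of 3 with 3 libraries. Statistics were run in R 4.3.3; tables were read and figures drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.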

Results

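Developing oligodendrocytes from mice without NRF2 (Nfe2l2, the transcription factor of the oxidative stress response) and from wild-type mice were compared in 50 bulk RNA-seq libraries. Oligodendrocyte precursors had been immunopanned from the cortices of C57BL/6 mouse pups, passaged, and allowed to differentiate for 12 to 14 h before treatment. A tissue tag names whole brain instead, and the design text speaks of more mutant replicates per group than the 3 in the series. Cells were left untreated or received 200 U/ml IFN-γ, an inflammatory cytokine, for 1, 8, 24 or 48 h, or thapsigargin, which empties the calcium store of the endoplasmic reticulum (ER), for 1 or 8 h. The thapsigargin dose is labelled as 200 µM. Each of the 20 groups holds 2 wild-type or 3 Nrf2 -/- libraries, with 32.3 to 54.7 M counted reads per library (median 36 M), and 16460 genes were tested. A single count of called list members is the same when adjusted over the list alone, and camera calls in the responses to treatment printed without a further value held with an estimated correlation. For called genes named below, every treated library lay on the same side of every untreated library of that hour and genotype unless stated.

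Nfe2l2 (ENSMUSG00000015839.6, GRCm38 chromosome 2, 75675513 to 75704641) separated the genotypes in nearly every library. In wild-type cells it stood at 7.26 to 10.29 CPM at 1 h, at 5.12 and 10.13 CPM in untreated cells at 8 h, and at 20.74 to 28.68 CPM at 24 h. With IFN-γ at 8 h it held 15.83 and 19.42 CPM and with thapsigargin 17.18 and 17.34 CPM. At 48 h it reached 64.83 and 70.43 CPM in untreated cells and 30.08 and 38.28 CPM with IFN-γ. Nrf2 -/- libraries held 0.10 to 0.86 CPM, except the library labelled Nrf2 -/- untreated 8 h replicate 3, which held 7.62 CPM. The 3 libraries with conflicting genotype labels all had the low level of the mutants. Averaged over hours, Nfe2l2 was lower in Nrf2 -/- cells by a log2 fold of −4.82 ± 0.33 SE untreated (12 against 8 libraries, edgeR BH-adjusted p = 4.17e-11, 95% interval −5.49 to −4.15). The edgeR log2 fold was −6.10 ± 0.36 with IFN-γ (12 against 8, BH-adjusted p = 9.76e-13) and −4.45 ± 0.46 with thapsigargin (6 against 4, 1.67e-06). With the 3 conflicting libraries counted as wild type, the thapsigargin value was −4.15 ± 0.85 with an edgeR BH-adjusted p of 0.473.

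**Figure D1:**
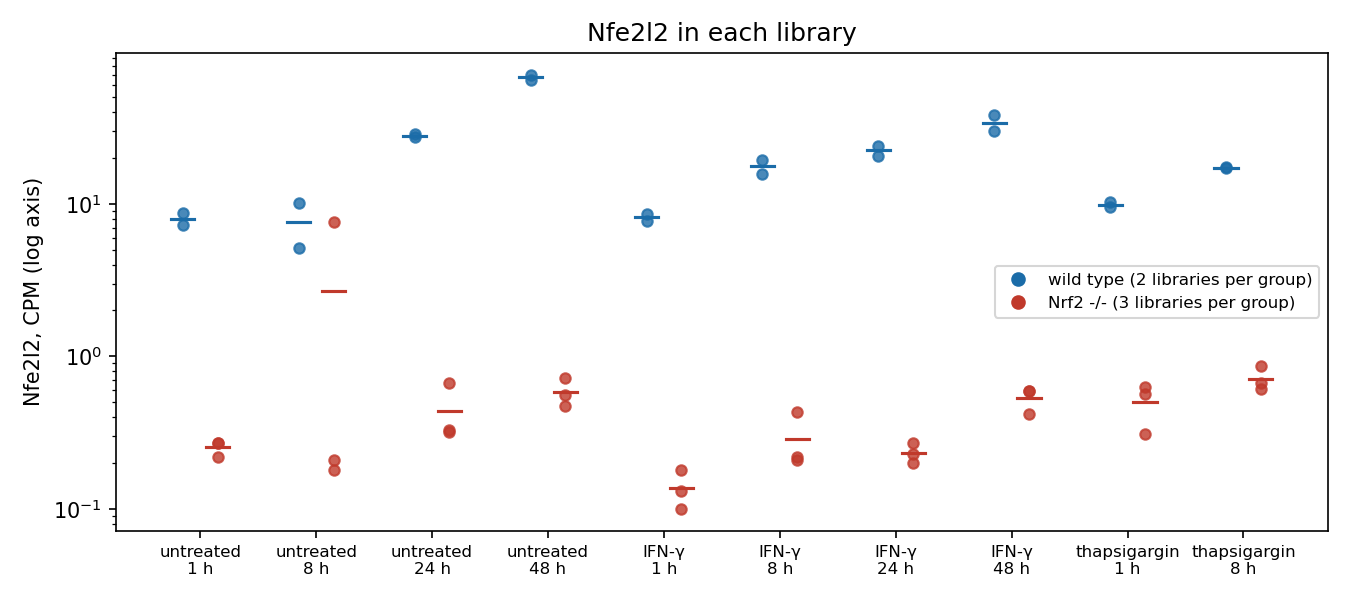
Nfe2l2 in each of the 50 libraries, in CPM on a log axis by treatment and hour; points are libraries and short lines are group means. All Nrf2 -/- libraries lie at or below 0.86 CPM except 1 at 7.62 CPM in the untreated 8 h group.

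Loss of NRF2 left the transcriptome of untreated cells close to wild type. Besides Nfe2l2, Scn3a, a voltage-gated sodium channel, was higher (1.08 ± 0.20), as was Mettl8, an RNA methyltransferase (0.34 ± 0.05), while the myelin-sheath gene Ermn was lower (−0.74 ± 0.13). These were all 4 of the genes past the threshold (2 higher, 2 lower, 12 against 8 libraries over 4 hours), with edgeR BH-adjusted p of 0.0218 for Scn3a, 0.000113 for Mettl8 and 0.00606 for Ermn. For each of them the means differed in the same direction at all 4 hours. Leaving out the library labelled Nrf2 -/- untreated 8 h replicate 3 or Nrf2 -/- untreated 24 h replicate 1 gave 7 genes each. The 8 h library is low in Xist, and without it Xist itself passed (7.42 ± 1.45, edgeR BH-adjusted p = 0.0441), while the 24 h library is high in Xist. Scn3a was lost without wild-type untreated 1 h replicate 1 (edgeR BH-adjusted p = 0.175), 8 h replicate 2 (0.121), 24 h replicate 2 (0.267) or 48 h replicate 1 (0.131). Ermn was lost without wild-type untreated 1 h replicate 2 (0.0680) or 8 h replicate 1 (0.0697). With a term for high Xist neither Scn3a (0.196) nor Ermn (0.103) passed, while Mettl8 did (0.00183). DESeq2 called 14 genes. On simulated data, a 1.5-fold difference in this comparison was recovered in 26 of 26 genes at 5 CPM or more. The simulated libraries were independent, without differences of sex or culture. The simulation also changed 200 genes and gave 155 calls against the 4 real ones, which made its adjusted threshold less strict. This rate may thus not hold for the real libraries, where Ly75 at 0.78 ± 0.18 did not pass (edgeR BH-adjusted p = 0.189).

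Averaged over hours, the classical NRF2 targets did not differ by genotype past the threshold. In untreated cells the log2 folds and 95% intervals were 0.40 (−0.12 to 0.92) for the quinone reductase Nqo1, 0.13 (−0.02 to 0.29) for heme oxygenase Hmox1, −0.06 (−0.12 to 0.01) for Gclc and −0.01 (−0.09 to 0.08) for Gclm, the subunits of the glutathione-synthesis enzyme. They were −0.03 (−0.08 to 0.02) for thioredoxin reductase Txnrd1, 0.01 (−0.10 to 0.12) for Srxn1 and −0.02 (−0.60 to 0.56) for the cystine transporter Slc7a11. The intervals of Nqo1 and Slc7a11 are wide. Their change from 1 to 48 h in untreated cells, Nrf2 -/- minus wild type, differed by −1.30 for Nqo1 (−2.58 to −0.01, edgeR BH-adjusted p = 0.681). For Slc7a11 it was −0.94 (−1.97 to 0.08, 0.74), and for the other targets named here −0.17 to −0.01. Of 30 measured NRF2 targets 0 were called in each of the 3 genotype comparisons by edgeR, and the list medians were −0.02 untreated, −0.04 with IFN-γ and −0.02 with thapsigargin. With IFN-γ, 2 targets fell when adjusted over the list alone, and camera placed the list lower (BH-adjusted p = 0.00455), a call lost at an adjusted p = 0.34 with an estimated correlation and without wild-type IFN-γ 48 h replicate 1 (median −0.03, 0.0937). In untreated cells the list passed camera only without wild-type untreated 1 h replicate 1 (median −0.01, 0.0309). Me1, an NADPH-supplying NRF2 target, was lower with IFN-γ in edgeR without Nrf2 -/- IFN-γ 24 h replicate 3 (−0.24 ± 0.04, BH-adjusted p = 0.0112) or wild-type IFN-γ 48 h replicate 2 (−0.22 ± 0.05, 0.0317), and in DESeq2 with all libraries (−0.20 ± 0.05, 0.0303). Nqo1 (0.19, −0.52 to 0.89) and Hmox1 (−0.02, −0.22 to 0.18) did not differ with thapsigargin either, a treatment that raised Hmox1 in both genotypes.

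Averaged over hours, untreated Nrf2 -/- cells differed little from wild type in cell-cycle, cholesterol and myelin lists. The cell-cycle list had a median of 0.12 (0 of 24 called, camera BH-adjusted p = 2.02e-08), cholesterol synthesis 0.07 (0 of 23 called, 4.86e-05) and the myelin list −0.08 (1 of 28 fell, Ermn, 2.83e-06). All 3 calls were lost at an adjusted p = 0.45 with an estimated correlation. With a term for high Xist the cell-cycle median was 0.05 (camera BH-adjusted p = 0.106) and the myelin median 0.01 (0.532). By hour the cell-cycle median was 0.43, 0.07, 0.15 and −0.17 at 1, 8, 24 and 48 h. Camera also called the MHC class I, progenitor, astrocyte and mitochondrial lists, with medians of 0.09, 0.05, −0.14 and −0.11, but each of these calls was lost without any of several single libraries and with an estimated correlation.

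With IFN-γ the genotype difference was again small and lay largely on chromosome 2, where Nfe2l2 itself sits. Scn3a (1.11 ± 0.20) and Mettl8 (0.43 ± 0.05) were higher as in untreated cells, joined by Ly75, an endocytic receptor of immune cells (0.77 ± 0.13), Tshz2 (0.23 ± 0.04), the cilium gene Ttc21b (0.20 ± 0.04) and Ccdc173 (0.57 ± 0.09). The laminin receptor subunit Itga6 (−0.59 ± 0.10) and the homeobox gene Dbx2 (−1.05 ± 0.21) were lower. With Nfe2l2 this made 9 genes (6 higher, 3 lower, 12 against 8 libraries), with edgeR BH-adjusted p from 5.09e-07 for Mettl8 to 0.0266 for Dbx2. Scn3a, Mettl8, Ly75, Ttc21b, Ccdc173 and Itga6 lie within 20 Mb of Nfe2l2, at 3.9 to 15.4 Mb. Single libraries mattered for 4 of these genes in edgeR. Scn3a was lost without wild-type replicate 2 of 8 h (BH-adjusted p = 0.0626) or 24 h (0.0506) or replicate 1 of 48 h (0.0530), and Tshz2 without wild-type 1 h replicate 2 (0.0939), 8 h replicate 1 (0.110) or 48 h replicate 1 (0.0530). Ttc21b was lost without wild-type 1 h replicate 1 (0.0858), 8 h replicates 1 (0.110) or 2 (0.0761) or 24 h replicate 2 (0.0720), or Nrf2 -/- 24 h replicate 2 (0.0726) or 48 h replicate 3 (0.0640). Dbx2 was lost without wild-type 1 h replicate 2 (0.149), 8 h replicate 1 (0.166), 24 h replicates 1 (0.0593) or 2 (0.0605) or 48 h replicate 1 (0.0640), or Nrf2 -/- 8 h replicate 2 (0.0858), 24 h replicate 1 (0.0848) or 48 h replicate 2 (0.0511). With a term for high Xist, Scn3a (0.99 ± 0.22, edgeR BH-adjusted p = 0.111), Ttc21b (0.20 ± 0.05, 0.111) and Dbx2 (−1.04 ± 0.25, 0.15) had similar folds with larger errors and did not pass, and Ly75 (0.58 ± 0.14, 0.164) and Tshz2 (0.16 ± 0.05, 0.604) had smaller folds and did not pass. The number of called genes rose to 20 without wild-type IFN-γ 1 h replicate 1, to 27 without Nrf2 -/- IFN-γ 1 h replicate 2, to 15 without Nrf2 -/- IFN-γ 8 h replicate 3 and to 121 (100 higher, 21 lower) without wild-type IFN-γ 48 h replicate 2. DESeq2 called 53.

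**Figure D2:**
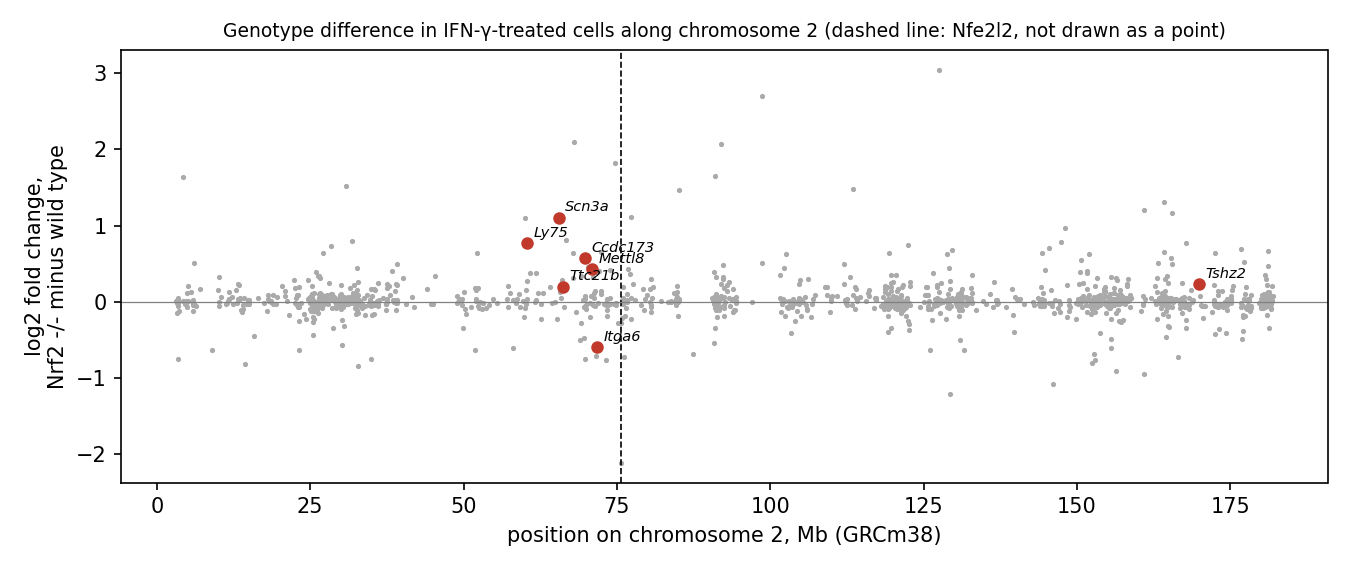
Genotype difference of each tested gene on chromosome 2 in IFN-γ-treated cells. The horizontal axis is position in Mb (GRCm38) and the vertical axis the log2 fold change, with called genes in red. The dashed line is Nfe2l2, not drawn as a point, and 6 called genes lie within 20 Mb of it.

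Among lists in IFN-γ-treated cells, the cell cycle was higher in Nrf2 -/- cells (median 0.20, camera BH-adjusted p = 2.73e-19, 0 of 24 called over all genes, 17 rose adjusted over the list alone, adjusted p = 0.30 with an estimated correlation). Myelin genes were lower (median −0.11, 0 of 28 called, 2 fell adjusted over the list alone, camera BH-adjusted p = 6.36e-07, adjusted p = 0.34 with an estimated correlation), and with a term for high Xist the median was −0.01 (0.153). MHC class I genes leaned lower as well (−0.09, 0 called, camera BH-adjusted p = 0.00455, adjusted p = 0.53 with an estimated correlation). That call was lost without wild-type IFN-γ 1 h replicate 2 (median −0.05, 0.0576).

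Thapsigargin-treated Nrf2 -/- cells carried more cell-cycle transcripts than wild-type cells. The kinetochore gene Spc25 (0.90 ± 0.13), the chromatin assembly gene Chaf1b (0.87 ± 0.20) and the mitotic genes Plk1 (0.57 ± 0.12), Ccnb1 (0.57 ± 0.12) and Nusap1 (0.55 ± 0.12) were higher. Of 24 cell-cycle genes 11 rose and 22 rose adjusted over the list alone (median 0.45, camera BH-adjusted p = 5.18e-40, adjusted p = 0.015 with an estimated correlation). In all 84 genes passed (77 higher, 7 lower, 6 against 4 libraries), with an edgeR BH-adjusted p of 0.000154 for Spc25, which lies 6.5 Mb from Nfe2l2. A term for high Xist, chosen after the data were seen, left 3 genes past the threshold. The count was 2 without wild-type thapsigargin 1 h replicate 2, 8 h replicate 2 or Nrf2 -/- thapsigargin 8 h replicate 2, 4 without Nrf2 -/- thapsigargin 1 h replicate 3 and 50 without Nrf2 -/- thapsigargin 1 h replicate 1. Without these 5 libraries in that order, edgeR BH-adjusted p was 0.275, 0.148, 0.0920, 0.0662 and 0.0516 for Ccnb1 and 0.276, 0.222, 0.137, 0.0954 and 0.0518 for Nusap1. For Plk1 it was 0.256, 0.119, 0.0824 and 0.0662 without the leading 4, and for Chaf1b 0.240, 0.452, 0.0824 and 0.0843, with 0.162 without Nrf2 -/- thapsigargin 8 h replicate 1. Spc25 stayed past the threshold in each of these 5 runs. Leaving out the 3 libraries with conflicting labels left 4 genes, Spc25 among them (0.85 ± 0.13), and counting them as wild type left 0 (Spc25 0.58 ± 0.17, 0.594). Myelin genes had a median of −0.17 (1 fell adjusted over the list alone, camera BH-adjusted p = 2.48e-06, adjusted p = 0.69 with an estimated correlation), lost without wild-type thapsigargin 8 h replicate 1 (median −0.09, 0.114).

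IFN-γ raised its classical target genes within 1 h in both genotypes. In wild-type cells the immunity-related GTPase genes Irgm2 (8.15 ± 0.53) and Igtp (9.65 ± 0.94), the immunoproteasome subunit Psmb9 (4.36 ± 0.34) and the MHC class I activator Nlrc5 (3.95 ± 0.34) rose, and Tgtp2 went from 0 counts to 14.37 CPM (at least 370-fold). Nrf2 -/- cells raised Irgm2 (7.75 ± 0.45), Psmb9 (4.18 ± 0.28), the peptide transporter Tap1 (2.80 ± 0.16) and the transcription factor Irf8 (5.28 ± 0.24). The growth-factor response gene Egr2 (2.65 ± 0.26 and 2.33 ± 0.21) and Jun (1.71 ± 0.18 and 1.37 ± 0.14) rose in wild-type and Nrf2 -/- cells. The kinase genes Sgk1 (−0.83 ± 0.11, wild type) and Sik1 (−0.80 ± 0.14 and −0.94 ± 0.12) fell. Reads of the Gbp, Irg, Tgtp and H2-Q families may be shared between paralogs, which makes single members less certain than the families.

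At 1 h edgeR called 345 genes in wild type (285 higher, 60 lower, 2 against 2 libraries) and 364 in Nrf2 -/- (280 higher, 84 lower, 3 against 3). The wild-type count was 219 without untreated replicate 1, 197 without untreated replicate 2 and 209 without IFN-γ replicate 2. MHC class I genes rose (8 and 7 of 20, 11 and 9 adjusted over the list alone, medians 0.57 and 0.20, camera BH-adjusted p = 1.63e-23 and 1.24e-18). Among type I interferon-stimulated genes 7 and 8 of 25 rose, 12 and 10 adjusted over the list alone (medians 1.05 and 0.95, camera BH-adjusted p = 5.53e-15 and 1.81e-15). Among p53 and cell-death genes 4 of 16 rose in wild type (5 adjusted over the list alone), including the death receptor Fas (1.96 ± 0.32; median 0.12, camera BH-adjusted p = 0.00165, adjusted p = 0.052 with an estimated correlation). In Nrf2 -/- 3 of 16 rose (4 up and 1 down adjusted over the list alone, median −0.01, 0.0995). NF-κB and chemokine genes did not pass in wild type (2 of 13 rose, 3 adjusted over the list alone, median 0.01, camera BH-adjusted p = 0.162). They passed in Nrf2 -/- (2 of 13, 3 adjusted over the list alone, median 0.03, 0.00693, adjusted p = 0.10 with an estimated correlation).

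By 8 h interferon genes had risen steeply. GTPase genes that were silent in untreated wild-type cells became abundant: Ifi47 reached 816.8 CPM (at least 21600-fold) and Gbp4 756.9 CPM (at least 20000-fold), and in Nrf2 -/- cells Gbp10 reached 170.6 CPM (at least 6530-fold). Antigen presentation followed with Psmb9 (8.58 ± 0.33 in wild type, 8.90 ± 0.28 in Nrf2 -/-), the nonclassical H2-T23 (8.71 ± 0.34 in wild type) and the class II activator Ciita (at least 444-fold in wild type). So did the antiviral gene Ifit1 (11.06 ± 0.46 and 10.75 ± 0.37). The inflammatory caspase genes Casp12 (9.58 ± 0.35 and 8.07 ± 0.25) and Casp4 (6.08 ± 0.26 and 6.19 ± 0.21) rose steeply. Jun (4.02 ± 0.19 and 3.93 ± 0.16), Egr2 (5.33 ± 0.32 and 6.06 ± 0.28), the neuronal tubulin Tubb3 (2.48 ± 0.13 and 2.43 ± 0.10) and carbonic anhydrase Car2 (5.46 ± 0.28 and 4.89 ± 0.22) rose outside the classical programme. The planar-polarity kinesin Kif26a (−3.30 ± 0.16 and −3.29 ± 0.13) and Shisa9 (−3.93 ± 0.35 and −3.88 ± 0.28), a glutamate-receptor regulator, were among the steepest falls.

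Counts at 8 h were 4338 in wild type (2250 higher, 2088 lower) and 5052 in Nrf2 -/- (2654 higher, 2398 lower). All 20 MHC class I genes rose in both genotypes (medians 5.48 and 5.54, camera BH-adjusted p = 5.20e-135 and 3.03e-139). All 7 measured MHC class II genes rose too (medians 3.87 with floor bounds and 3.30, camera BH-adjusted p = 2.92e-09 and 5.42e-11). Also up in both were 24 of 25 type I interferon-stimulated genes (camera BH-adjusted p = 1.17e-114 and 8.39e-121). p53 and cell-death genes rose in 8 of 16 in each genotype (medians 0.61 and 0.31, camera BH-adjusted p = 1.41e-09 and 6.40e-10). Immediate early genes rose in 12 and 9 of 18 (12 in each adjusted over the list alone, medians 0.74 and 0.67, 0.000220 and 0.000233, adjusted p = 0.11 and 0.10 with an estimated correlation). Neuron markers rose in 7 and 6 of 13 (7 in each adjusted over the list alone, medians 0.71 and 0.46, 0.00563 and 0.0251, adjusted p = 0.015 and 0.060 with an estimated correlation). ER chaperones fell in 8 and 7 of 16 (medians −0.22 and −0.13, camera BH-adjusted p = 0.0326 and 0.152, adjusted p = 0.57 and 0.72 with an estimated correlation). In the mature myelin list 15 fell and 1 rose of 28 in wild type and 17 fell and 1 rose in Nrf2 -/- (18 and 20 fell and 2 and 1 rose adjusted over the list alone, medians −0.66 and −0.63, camera BH-adjusted p = 0.00196 and 0.00129, adjusted p = 0.46 and 0.44 with an estimated correlation). Mog (−1.53 ± 0.20) and Opalin (−1.40 ± 0.17) fell in wild type. Precursor regulators moved in opposite ways, Sox11 up (2.03 ± 0.12 and 1.72 ± 0.09) and Gpr17 down (−1.38 ± 0.11 and −1.43 ± 0.09).

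At 24 h cholesterol-synthesis and myelin genes fell while cell-cycle genes rose. All 23 cholesterol-synthesis genes fell in both genotypes (medians −1.46 and −1.54, camera BH-adjusted p = 8.99e-27 and 4.45e-31, adjusted p = 0.0074 and 0.0034 with an estimated correlation). Lss (−2.27 ± 0.13 and −2.27 ± 0.10) and Mvd (−2.02 ± 0.13 and −2.17 ± 0.11) were among them. All 24 cell-cycle genes rose (medians 1.69 and 1.61, 1.40e-17 and 3.30e-17, adjusted p = 0.066 and 0.060 with an estimated correlation), for example the mitotic cyclin Ccnb2 (2.05 ± 0.17 and 1.83 ± 0.13) and the replication gene Mcm3 (1.93 ± 0.15 in wild type). Of 28 myelin genes 22 fell and 1 rose in each genotype (23 and 22 fell and 3 and 1 rose adjusted over the list alone, medians −1.09 and −1.18, 1.20e-08 and 2.89e-10, adjusted p = 0.095 and 0.060 with an estimated correlation). Among them were Opalin at −3.57 ± 0.17 and −3.74 ± 0.14 and Mog at −2.81 ± 0.20 and −2.91 ± 0.17. The precursor proteoglycan Cspg5 rose (1.85 ± 0.10 and 1.45 ± 0.08) in a direction opposite to its fall in untreated wild-type cells over 48 h (−2.29 ± 0.10). Gene counts were 7110 in wild type (3570 higher, 3540 lower) and 7788 in Nrf2 -/- (3719 higher, 4069 lower).

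Interferon genes remained high at 24 h. Gbp2 went from 0 counts to 6873 CPM in wild type (at least 147000-fold), the class I gene H2-Q6 to 77.95 CPM (ratio 4990, 95% interval 896 to 197000) and Casp12 rose by 9.15 ± 0.34 in wild type and 8.18 ± 0.25 in Nrf2 -/-. All 20 MHC class I genes (medians 7.36 and 6.99) and all 7 class II genes (6.00 with floor bounds and 6.07) rose. So did 11 of 16 p53 and cell-death genes (medians 0.75 and 0.68, camera BH-adjusted p = 1.92e-07 and 8.00e-08). NRF2 targets split in both genotypes, 7 up and 8 down in wild type and 8 up and 12 down of 30 in Nrf2 -/- (9 up and 9 down, then 8 up and 13 down adjusted over the list alone, camera BH-adjusted p = 0.893 and 0.474). The NADPH-supplying Me1 fell (−1.60 ± 0.11 and −1.81 ± 0.09) and Ugdh rose (1.14 ± 0.12 in wild type).

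After 48 h of IFN-γ ER chaperones were higher than in untreated cells of that hour, and most myelin genes were lower. Hspa5, the main ER chaperone (0.64 ± 0.08 and 0.63 ± 0.06), Calr (0.72 ± 0.09 and 0.71 ± 0.07), Creld2 (0.90 ± 0.10 and 0.74 ± 0.08) and the transcription factor Xbp1 (1.10 ± 0.11 and 0.87 ± 0.09) rose. In the list, 13 and 11 of 16 ER chaperones and ATF6 targets rose (medians 0.41 and 0.29, camera BH-adjusted p = 0.00237 and 0.0162, adjusted p = 0.47 and 0.58 with an estimated correlation). In untreated wild-type cells Creld2 had itself fallen, from 28.6 CPM at 1 h to 15.5 CPM at 48 h, against 28.9 CPM with IFN-γ at 48 h. Of 28 myelin genes 20 fell in each genotype (20 and 23 adjusted over the list alone, medians −1.12 and −1.08, 4.42e-07 and 1.44e-08, adjusted p = 0.24 and 0.16 with an estimated correlation). Ermn stood at −3.49 ± 0.18 and −3.79 ± 0.16 and Mal at −3.41 ± 0.21 and −3.38 ± 0.17. Mog, lower at 8 and 24 h, overlapped in wild type (41.6 against 47.5 CPM, edgeR BH-adjusted p = 0.435) and was lower in Nrf2 -/- (36.1 against 51.8 CPM, 0.00437). Of 16 p53 and cell-death genes 5 rose and 9 fell in wild type and 5 rose and 8 fell in Nrf2 -/- (medians −0.55 and −0.57, camera toward higher in both with BH-adjusted p = 0.23 and 0.301). MHC class II genes reached their highest bounded medians (6.44 and 7.24), with H2-Eb1 at 8.96 ± 0.38 in wild type. Cell-cycle genes rose in 19 and 22 of 24 (19 and 23 adjusted over the list alone, medians 0.54 and 0.87, camera BH-adjusted p = 0.0116 and 5.51e-06, adjusted p = 0.77 and 0.56 with an estimated correlation). The wild-type call was lost without IFN-γ replicate 1 (median 0.44, 0.0841). Cholesterol synthesis was no longer lower in wild type (5 up, 5 down, median −0.04, 0.817), while 14 of 23 genes fell in Nrf2 -/- (15 adjusted over the list alone, median −0.37, 0.0162, adjusted p = 0.80 with an estimated correlation). The difference between the genotypes was −0.33 for cholesterol synthesis (camera BH-adjusted p = 1.65e-11, adjusted p = 0.74 with an estimated correlation). Counts were 7092 in wild type (3474 higher, 3618 lower) and 7466 in Nrf2 -/- (3746 higher, 3720 lower), and the wild-type count fell to 4720 without IFN-γ replicate 1.

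**Figure D3:**
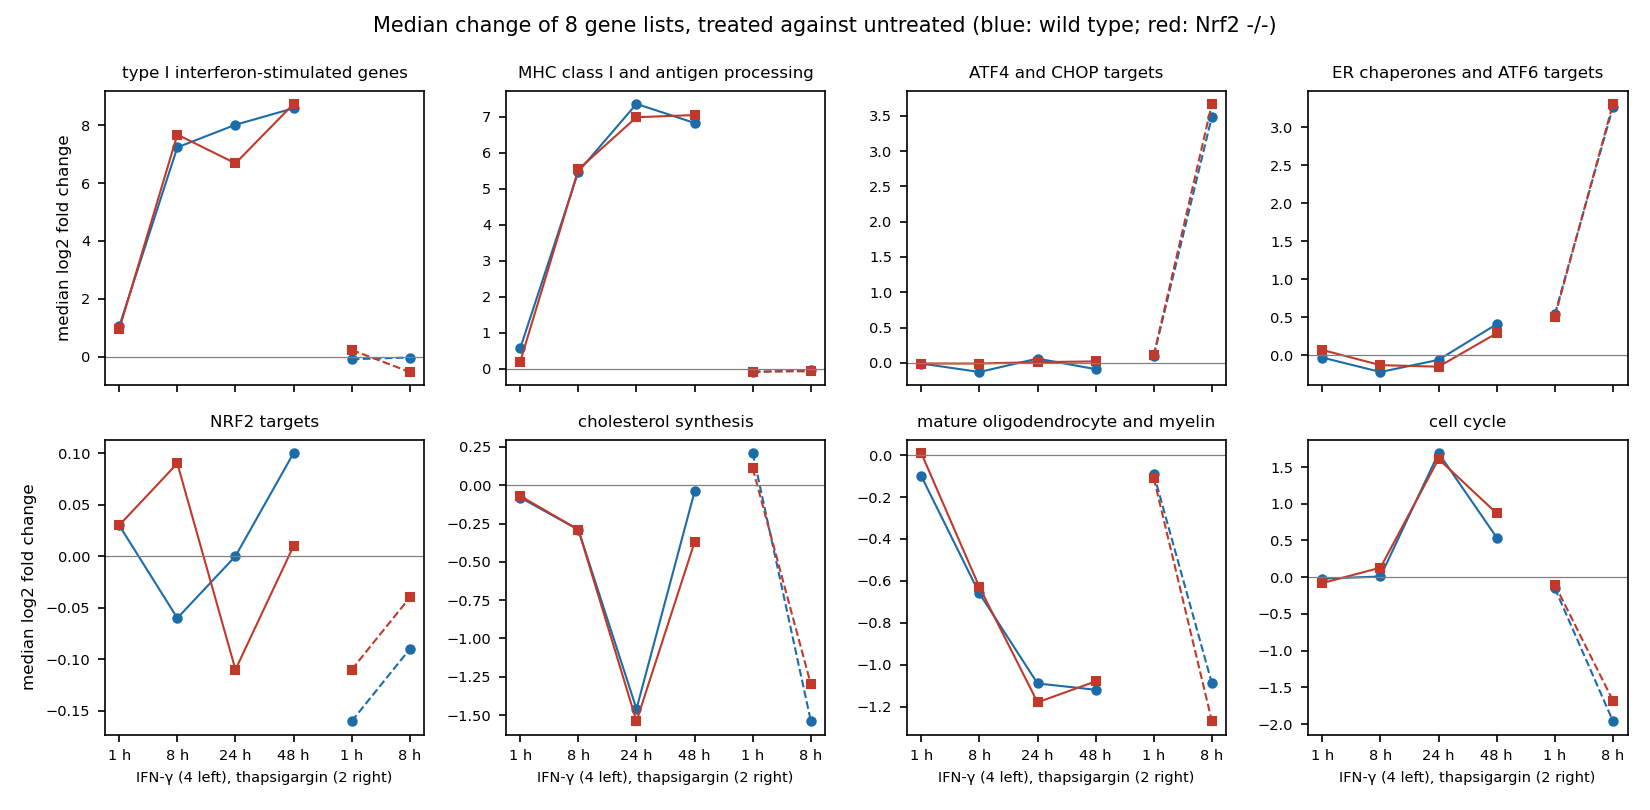
Median log2 fold change of 8 gene lists after IFN-γ (left 4 points of each panel) or thapsigargin (right 2 points). Wild type is blue and Nrf2 -/- red. Vertical scales differ between panels, and the medians use fitted folds without floor bounds. At 48 h of IFN-γ cholesterol synthesis stood at −0.04 in wild type and −0.37 in Nrf2 -/-.

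For the difference between the genotypes' responses to IFN-γ, edgeR called 0 genes each at 1, 8, 24 and 48 h (unadjusted p below 0.05 in 486, 427, 1237 and 1366 genes), and DESeq2 called 1, 2, 13 and 5 (unadjusted 543, 417, 1289 and 1401). The edgeR counts are 3%, 2.6%, 7.5% and 8.3% of tested genes. At 1 and 8 h that is under the share chance alone gives at p below 0.05, so 0 calls there do not show equal responses. The DESeq2 calls, named here after their values were seen, were Gbp4 at 1 h, Gbp4 and Gm4951 at 8 h, Ppig, Gbp4, Gcc2, Zfp62, Arid4b, Ddx46, Zfyve16, Pcdh9, Phf20l1, Usp7, Gm4951, Smc5 and Eif3a at 24 h and Fbxl5, Elfn1, Homer1, Pou6f1 and Gm4951 at 48 h. The smallest edgeR BH-adjusted p was 0.0796, at 48 h. Across genes called in either genotype (452, 5760, 8979 and 8967) the Pearson correlation of log2 folds was 0.936, 0.948, 0.911 and 0.944 (Spearman 0.947, 0.933, 0.925 and 0.922), with orthogonal slopes of Nrf2 -/- on wild type of 0.881 at 1 h, 0.955 at 8 h and 0.84 at 24 h, and closer to 1 at 48 h. These correlations run across genes, which are not independent replicates. The 24 h slope includes Nrf2 -/- untreated replicate 2, which held 40.61 CPM of the interferon gene Gbp2. The other untreated 24 h libraries held at most 0.16 CPM, and a slope without that replicate was not computed. At 8 h 1994 genes rose in both (362.8 by chance) and 1635 fell in both (304.2 by chance). In 10567 genes with at least 5 CPM the 95% interval of the difference lay within 2-fold for 93% to 95.9% of genes over all 7 such comparisons. For Nfe2l2 at 8 h the difference between responses was −4.46 ± 0.99 and did not pass (edgeR BH-adjusted p = 1). It passed in edgeR without Nrf2 -/- untreated 8 h replicate 1 (−5.00 ± 0.82, 0.0199) or replicate 2 (−5.02 ± 0.81, 0.013), giving 1 gene each. In these runs the untreated mutant mean rests more on replicate 3, which held 7.62 CPM against 0.21 and 0.18 CPM in the others; without replicate 3 the difference was −0.72 ± 0.57. Without wild-type untreated 24 h replicate 1 the 24 h count was 40. At 48 h it was 12 without wild-type untreated replicate 1, 770 without wild-type IFN-γ replicate 2, 1 without Nrf2 -/- untreated replicate 1 and 5 without replicate 3.

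Thapsigargin set off the unfolded protein response within 1 h. The stress transcription factor Ddit3 (CHOP) rose by 3.61 ± 0.13 in wild type and 2.99 ± 0.11 in Nrf2 -/-. Herpud1 of ER-associated degradation rose by 2.10 ± 0.09 and 1.74 ± 0.07, Hspa5 by 1.05 ± 0.08 and 1.01 ± 0.06 and Xbp1 by 1.85 ± 0.11 and 1.63 ± 0.09. Calcium-responsive genes rose alongside, with Egr1 (3.74 ± 0.41 and 3.28 ± 0.33) and Nr4a1 (2.97 ± 0.13 and 2.99 ± 0.11). The RNA-binding gene Mex3b (−1.52 ± 0.09 and −1.22 ± 0.08) and the microRNA host Mir17hg (−1.42 ± 0.13 and −1.49 ± 0.10) fell. Of 18 immediate early genes 15 and 16 rose and all 18 rose adjusted over the list alone (medians 2.21 and 1.92, camera BH-adjusted p = 3.71e-55 and 8.85e-71). Of 16 ER chaperones 14 rose in each genotype (medians 0.54 and 0.51, 1.67e-38 and 8.20e-49), and 10 and 9 of 29 ATF4 and CHOP targets had risen (10 in each adjusted over the list alone, 1.57e-10 and 6.61e-10, adjusted p = 0.0036 and 0.0056 with an estimated correlation). Glutathione and thiol genes outside the NRF2 list fell in 3 and 2 of 24 (4 and 2 adjusted over the list alone, medians −0.18 and −0.12, 0.00256 and 0.013, adjusted p = 0.20 and 0.23 with an estimated correlation).

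At 1 h edgeR called 1486 genes in wild type (1100 higher, 386 lower) and 1529 in Nrf2 -/- (1248 higher, 281 lower). The wild-type count was 949 without untreated replicate 1, 674 without untreated replicate 2, 696 without thapsigargin replicate 1 and 969 without thapsigargin replicate 2, and the Nrf2 -/- count was 992 without thapsigargin replicate 3. Of these, 864 genes rose in both genotypes (83.4 by chance).

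By 8 h thapsigargin had raised every ATF4 target measured and lowered cell-cycle genes, cholesterol-synthesis genes and most myelin genes. The kinase-like Trib3 rose by 10.21 ± 0.34 in wild type and 10.20 ± 0.28 in Nrf2 -/- and Slc7a11 by 10.46 ± 0.26 and 10.16 ± 0.21. The stress gene Nupr1 rose to 75.67 and 84.42 CPM (ratios 2000, interval 685 to 9700, and 3230, interval 1110 to 15700) and the ER-degradation gene Derl3 by 7.99 ± 0.28 and 8.07 ± 0.23. Secretory-pathway genes Sec24d (4.59 ± 0.13 and 4.61 ± 0.11) and Sel1l (3.37 ± 0.06 and 3.19 ± 0.05) rose as well. So did the p53 targets Cdkn1a (2.14 ± 0.14 and 1.92 ± 0.11) and Bbc3 (1.94 ± 0.16 and 2.16 ± 0.13), a death effector. Mog (−3.24 ± 0.23 and −3.15 ± 0.19) fell. So did Mcm3 (−3.45 ± 0.18 and −3.01 ± 0.14), Mvk (−2.52 ± 0.12 and −2.31 ± 0.09) and the antioxidant genes Glrx (−2.03 ± 0.15 and −2.33 ± 0.13) and Prdx2 (−1.40 ± 0.09 and −1.31 ± 0.08).

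Slc7a11 and Hmox1, both NRF2 targets, rose without NRF2. Hmox1 increased by 3.06 ± 0.16 in wild type and 3.16 ± 0.13 in Nrf2 -/- cells, from 7.93 ± 0.47 to 66.2 ± 12.0 CPM and from 8.32 ± 0.76 to 74.5 ± 5.68 CPM. The difference between the responses was 0.10 for Hmox1 (95% interval −0.30 to 0.50) and −0.30 for Slc7a11 (−1.49 to 0.89). As a list, NRF2 targets split evenly, 10 up and 12 down in wild type and 11 up and 12 down of 30 in Nrf2 -/- (12 and 13 down adjusted over the list alone, medians −0.09 and −0.04, camera BH-adjusted p = 0.513 and 0.392). Blvrb, which acts downstream of Hmox1 in heme breakdown, rose by 1.96 ± 0.22 and 1.87 ± 0.18.

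Thapsigargin changed 9136 genes at 8 h in wild type (4678 higher, 4458 lower) and 9868 in Nrf2 -/- (5002 higher, 4866 lower). All 29 ATF4 and CHOP targets rose (medians 3.49 and 3.67, camera BH-adjusted p = 9.34e-82 and 6.37e-89), all 16 ER chaperones and ATF6 targets rose (3.27 and 3.31, 3.90e-69 and 6.16e-76) and 19 of 20 XBP1 and ERAD genes rose (1.79 and 1.85, 1.72e-41 and 3.06e-44). All 24 cell-cycle genes fell (medians −1.96 and −1.68, 5.29e-18 and 2.09e-14, adjusted p = 0.085 and 0.16 with an estimated correlation), as did all 23 cholesterol-synthesis genes (−1.54 and −1.30, 6.27e-19 and 1.65e-15, adjusted p = 0.046 and 0.088 with an estimated correlation). In the myelin list 20 of 28 fell and 1 rose in each genotype (20 and 21 fell adjusted over the list alone, medians −1.09 and −1.27, 1.85e-06 and 5.59e-07, adjusted p = 0.26 and 0.22 with an estimated correlation). For the difference between the genotypes' responses to thapsigargin, edgeR with all libraries called 0 genes at 1 and 8 h (unadjusted p below 0.05 in 335 and 1376 genes) and DESeq2 called 1 (Gbp4) and 2 (Gm2237 and Gm4951, unadjusted 357 and 1424). The edgeR counts are 2% and 8.4% of tested genes, the 1 h share again under that given by chance alone. With edgeR 12 were called at 1 h with only libraries of the same time, and 201 at 8 h without wild-type thapsigargin replicate 1. Across genes called in either genotype, log2 folds correlated with a Pearson r of 0.818 at 1 h and 0.909 at 8 h (Spearman 0.855 and 0.930; slopes 0.846 and 0.97), and 3993 genes rose in both genotypes at 8 h (1421.6 by chance).

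Untreated cells of both genotypes matured between 1 and 48 h. Myelin genes rose steeply, with Mobp at 7.65 ± 0.38 in wild type and 7.53 ± 0.31 in Nrf2 -/- and Mal at 7.48 ± 0.28 and 7.08 ± 0.23. The precursor genes C1ql1 (−3.57 ± 0.19 and −3.24 ± 0.15) and Dll3 (−4.93 ± 0.24 and −4.64 ± 0.19) fell. Of 28 myelin genes 26 rose (medians 2.01 and 2.34, camera BH-adjusted p = 7.56e-20 and 9.37e-23, adjusted p = 0.021 and 0.0098 with an estimated correlation). Astrocyte markers rose in 9 and 8 of 14 and fell in 1 and 2 (10 and 8 rose adjusted over the list alone, medians 1.66 and 0.78, camera BH-adjusted p = 0.194 and 0.703). In the progenitor list 13 and 14 of 18 fell (−1.03 and −0.89, camera BH-adjusted p = 1.82e-05 and 6.26e-06, adjusted p = 0.021 and 0.0098 with an estimated correlation). Counts were 9006 in wild type (4774 higher, 4232 lower) and 10147 in Nrf2 -/- (5072 higher, 5075 lower), with a Pearson r across genes of 0.923 (Spearman 0.943). The difference between genotypes over time had 0 genes in edgeR (1200 at unadjusted p below 0.05, smallest BH-adjusted p 0.0841) and 14 in DESeq2 (1242 unadjusted). The edgeR count was 1 without wild-type untreated 48 h replicate 1 and 7 without Nrf2 -/- untreated 48 h replicate 3. Cell-cycle genes fell in 22 of 24 in Nrf2 -/- (median −0.88, camera BH-adjusted p = 0.000188, adjusted p = 0.90 with an estimated correlation) and in 8 of 24 in wild type (1 adjusted over the list alone, median −0.27, 0.321). The difference between genotypes in this list was −0.61 (camera BH-adjusted p = 4.83e-28, 21 genes adjusted over the list alone, adjusted p = 0.065 with an estimated correlation).

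Of markers of other cell types, 4 of 18 for microglia, 8 of 18 for endothelial, mural and fibroblast cells, 13 of 16 for neurons and 14 of 16 for astrocytes were measured. The microglia markers did not differ by genotype in untreated cells (median 0.04, camera BH-adjusted p = 0.526); nor did the neuron markers (0.06, 0.195) or endothelial markers (−0.08, 0 called by edgeR). P2ry12, a microglia marker that oligodendrocyte precursors can also express, rose with IFN-γ at 8 h in wild type (1.31 ± 0.20). Endothelial markers rose in 3 of 8 then (median 0.67, camera BH-adjusted p = 0.0368, adjusted p = 0.085 with an estimated correlation), a call lost without wild-type IFN-γ 8 h replicate 2 (0.31, 0.0852) or untreated 8 h replicate 1 (0.29, 0.132). Astrocyte markers fell in 6 and rose in 1 of 14 after 48 h of IFN-γ in wild type (8 fell adjusted over the list alone, median −0.84, 0.222) and fell in 6 and rose in 2 in Nrf2 -/- (7 fell adjusted over the list alone, median −0.92, 0.432). Mitochondrially encoded transcripts, in the same cells as the myelin and ER chaperone changes of 48 h, fell in 7 and rose in 1 of 10 (8 fell adjusted over the list alone, median −1.12, 0.0838), with mt-Cytb at −1.47 ± 0.23. In Nrf2 -/- 3 fell (median −0.56, 0.309). The wild-type list passed without wild-type untreated 48 h replicate 1 (−1.40, 0.00399). The 5 sex-linked genes had a median of −1.56 in untreated Nrf2 -/- against wild-type cells (camera BH-adjusted p = 0.0214, adjusted p = 0.45 with an estimated correlation; 1, Xist, rose adjusted over the list alone). That call was lost without Nrf2 -/- untreated 1 h replicate 1 (0.0542), 8 h replicate 1 (0.0751), 24 h replicate 2 (0.0518) or 48 h replicate 3 (0.0521). Each Nrf2 -/- group mixed 2 libraries high in Xist and 1 low, while every wild-type library was low, so sex and genotype are partly confounded.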

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

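Several gene lists differed between genotypes in their response by camera with a preset correlation, and none of these calls held with an estimated correlation. They are given as values. At 1 h of IFN-γ, Nrf2 -/- minus wild type, the response of MHC class I genes was lower by a median of −0.24 (camera BH-adjusted p = 0.00626, adjusted p = 0.67 with an estimated correlation), lost without Nrf2 -/- IFN-γ replicate 2 (0.137) or wild-type IFN-γ replicate 2 (−0.06, 0.253). ER chaperones stood at 0.09 (0.0341, adjusted p = 0.78 with an estimated correlation), lost without Nrf2 -/- IFN-γ replicate 2 (0.137), Nrf2 -/- untreated replicate 2 (0.175), wild-type IFN-γ replicate 1 (0.244) or wild-type untreated replicate 2 (0.165). Glutathione and thiol genes stood at 0.12 (0.000708, adjusted p = 0.46 with an estimated correlation).

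At 24 h of IFN-γ the MHC class I genes differed by a median of −0.50 (camera BH-adjusted p = 1.04e-06) and type I interferon-stimulated genes by −0.50 (0.0249), each with an adjusted p = 0.45 with an estimated correlation. Without Nrf2 -/- untreated 24 h replicate 2 MHC class I genes stood at −0.15 (0.0586) and type I genes at −0.25 (0.912). That untreated library held 40.61 CPM of the interferon gene Gbp2, against at most 0.16 CPM in the other untreated 24 h libraries. Type I genes were also lost without Nrf2 -/- IFN-γ replicate 1 (−0.46, 0.0515) or wild-type untreated replicate 1 (−1.10, 0.346). Smaller 24 h differences, all at an adjusted p = 0.45 with an estimated correlation, were −0.13 for NRF2 targets (camera BH-adjusted p = 0.0331), −0.12 for ATF4 and CHOP targets (0.0453), −0.13 for glutathione and thiol genes (0.0453) and 0.29 for mitochondrially encoded transcripts (0.0249). The NRF2-target call was lost without Nrf2 -/- IFN-γ replicate 1 (0.0851), Nrf2 -/- untreated replicate 2 (0.0559), wild-type IFN-γ replicate 2 (0.071) or wild-type untreated replicate 2 (0.197). ATF4 targets lost theirs without Nrf2 -/- IFN-γ replicates 1 (0.0851) or 2 (0.0766), Nrf2 -/- untreated replicates 1 (0.124) or 2 (0.0635), wild-type IFN-γ replicate 2 (0.11) or wild-type untreated replicates 1 (0.0976) or 2 (0.134). For glutathione genes this held without Nrf2 -/- IFN-γ replicate 1 (0.0851), Nrf2 -/- untreated replicates 1 (0.0744) or 2 (0.083), wild-type IFN-γ replicate 2 (0.17) or wild-type untreated replicate 2 (0.576). For mitochondrial transcripts it held without Nrf2 -/- IFN-γ replicates 1 (0.0789) or 2 (0.0766), Nrf2 -/- untreated replicates 2 (0.0559) or 3 (0.0597) or wild-type untreated replicate 2 (0.24).

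At 48 h of IFN-γ, cholesterol synthesis differed by −0.33 (camera BH-adjusted p = 1.65e-11, adjusted p = 0.74 with an estimated correlation) and the cell cycle by 0.30 (1.63e-07, adjusted p = 0.86 with an estimated correlation), the latter lost without wild-type IFN-γ replicate 2 (0.24, 0.278). At 8 h of thapsigargin, all at an adjusted p = 0.96 with an estimated correlation, the differences were 0.14 for ATF4 and CHOP targets (camera BH-adjusted p = 0.0495), 0.11 for ER chaperones (0.0164), 0.22 for cholesterol synthesis (4.17e-05) and 0.36 for the cell cycle (4.45e-06). ATF4 targets lost the call without Nrf2 -/- thapsigargin replicates 1 (0.599) or 3 (0.176), Nrf2 -/- untreated replicates 1 (0.177) or 3 (0.182), wild-type thapsigargin replicate 2 (0.92) or wild-type untreated replicate 2 (0.425). ER chaperones lost it without Nrf2 -/- thapsigargin replicate 3 (0.14), wild-type thapsigargin replicate 2 (0.92) or wild-type untreated replicate 1 (0.0704). The cell-cycle difference was 0.12 (adjusted p = 0.30) without the 2 doubted untreated 8 h libraries, an alternative chosen after the data were seen.

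Over 48 h without treatment, the differences were 0.17 for ER chaperones (camera BH-adjusted p = 5.53e-07, adjusted p = 0.16 with an estimated correlation), 0.24 for myelin genes (0.00322, adjusted p = 0.53 with an estimated correlation), 0.38 for cholesterol synthesis (1.30e-20, 14 genes adjusted over the list alone, adjusted p = 0.065 with an estimated correlation) and −0.61 for the cell cycle (4.83e-28, 21 genes adjusted over the list alone, adjusted p = 0.065 with an estimated correlation). Glutathione and thiol genes differed by 0.12 (0.0364, adjusted p = 0.45 with an estimated correlation) and astrocyte markers by −0.62 (0.00103, adjusted p = 0.16 with an estimated correlation). Myelin genes lost the call without wild-type untreated 1 h replicate 2 (0.10, 0.26), and astrocyte markers without wild-type untreated 48 h replicate 2 (−0.22, 0.113). Glutathione genes lost it without Nrf2 -/- untreated 1 h replicate 3 (0.0905), Nrf2 -/- untreated 48 h replicates 1 (0.0697) or 3 (0.0819), wild-type untreated 1 h replicate 2 (0.0969) or wild-type untreated 48 h replicate 2 (0.444).

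The genotype differences in untreated and IFN-γ-treated cells cluster on chromosome 2 around Nfe2l2; of the tests used here, the one on NRF2 acting genome-wide was written after the result was seen. If DNA from the strain in which the gene was targeted stayed linked to Nfe2l2, genes within 20 Mb should differ with thapsigargin as well, after leaving out those called with other treatments; 11.2% of 206 did at unadjusted p below 0.05, against 9.4% of 16244 (one-sided Fisher exact p = 0.217, odds ratio 1.22), so this explanation stays open, since the 6 against 4 libraries of that comparison give a weak test and all 213 nearby genes, those called elsewhere included, gave 13.1% against 9.4% (0.0437). Loss of NRF2 acting on genes across the genome would not place differences near Nfe2l2. That 7 of 9 called genes lie within 20 Mb (one-sided Fisher exact p = 1.94e-12), with Tshz2 (94.2 Mb away) and Dbx2 (chromosome 15) the exceptions, only restates the pattern. Of all 213 nearby genes, 17.4% untreated and 16.9% with IFN-γ reached unadjusted p below 0.05. Elsewhere 6.5% and 8.8% did (one-sided Fisher exact p = 7.22e-08 and 0.000143), and no NRF2 target was called in either. Action across the genome does not by itself account for the larger shares nearby. These shares come from the same comparisons as the pattern and include its called genes, so they are no separate test. With thapsigargin this explanation stays open. There 4 of 213 genes near Nfe2l2 were called against 79 of 16246 elsewhere, a larger share nearby (one-sided Fisher exact p = 0.0227) but most calls elsewhere. Sex of the cultures as the whole cause is argued against, as 7 of 7 nearby genes kept most of their fold with a term for high Xist, but with larger errors or smaller folds the calls ended for Scn3a (1.11 ± 0.20 to 0.99 ± 0.22 with IFN-γ, edgeR BH-adjusted p = 0.111), Ly75 (0.77 ± 0.13 to 0.58 ± 0.14, 0.164), Ttc21b (0.20 ± 0.04 to 0.20 ± 0.05, 0.111) and, untreated, Ermn (−0.74 ± 0.13 to −0.68 ± 0.15, 0.103), leaving Mettl8, Itga6 and Ccdc173 past the threshold. Sequence variants called from the reads of these libraries could decide between linked DNA and local regulation.

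The library labelled Nrf2 -/- untreated 8 h replicate 3 holds Nfe2l2 at the wild-type level; the test for a swap was written after the result was seen. A score over 6 other genes linked to Nfe2l2, 0 for the other Nrf2 -/- libraries of that group and 1 for wild-type untreated 8 h replicate 2 alone, gave 0.57 with a standard error of 0.17. Other libraries, each scaled within its own time and treatment, scored 0.49 to 2.02 (18 wild type) and −0.31 to 0.28 (29 Nrf2 -/-). Each of these wild-type libraries was scaled to the 1 other of its group. The 2 scores of a group are thus reciprocals, and their range does not measure the wild-type spread. The genes were those called in the IFN-γ genotype comparison, so in IFN-γ libraries the separation was fixed in advance. A wild-type library under a mutant label and a mixture with wild-type RNA both stay open, as the score lies between the Nrf2 -/- scores and 1. A full swap with wild-type untreated 8 h replicate 1 is argued against, because that library, which scored 0.45 ± 0.16, held 5.12 CPM of Nfe2l2, far above the mutants. Both libraries were kept, and the results without them are given with the other alternatives.

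Cell-cycle genes were higher in thapsigargin-treated Nrf2 -/- cells (median 0.45); the test for a difference without thapsigargin was written after the result was seen. In untreated cells at 1 and 8 h the list was higher by a median of 0.26 (13 of 24 rose adjusted over the list alone). At 1 h the median was 0.43 untreated and 0.46 with thapsigargin (21 of 24 rose adjusted over the list alone in each), so at that hour the difference was present without thapsigargin. At 8 h the medians were 0.07 and 0.46 (0 and 14). The untreated value rests in part on the 2 doubted libraries. Their mean log2 CPM over the list was 5.29 (Nrf2 -/- replicate 3) and 5.51 (wild-type replicate 1). The other untreated 8 h libraries stood at 5.56 and 5.62 (Nrf2 -/-) and 5.30 (wild type). Without the doubted libraries the genotypes' responses to thapsigargin at 8 h differed by a median of 0.12, against 0.36 with them. As that leaves 1 untreated wild-type library, for that hour the question stays open. With a term for high Xist the median stayed at 0.36, so sex as the whole cause is argued against, although the term took the calls from 84 to 3 genes and Plk1 from 0.57 ± 0.12 to 0.44 ± 0.12. At 24 and 48 h the untreated medians were 0.15 and −0.17, and whether the difference may reflect stage or density of the cultures was not tested.

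Genotype labels were exchanged between libraries of the same hour and treatment. As many genes as the real grouping gave came from 1 of 100 splits in untreated cells (3 genes in a fit of that treatment alone, highest other split 0), from 4 of 100 with IFN-γ (5 genes, highest other 1460) and from 2 of 100 with thapsigargin (44 genes, highest other 97), each count with the real split included. Without Nfe2l2 itself, a count made after these were seen, the real groupings gave 2, 4 and 43 genes, reached by 1, 5 and 2 of 100 splits, so chance is not excluded for the other genes with IFN-γ. For untreated and thapsigargin-treated cells it is excluded only if libraries of different hours are independent, which the labels do not show. The 1460 genes of another IFN-γ split point to a structure of the samples other than genotype, and the thapsigargin split with 97 genes held all 4 high-Xist libraries on one side, as the real one does. Within Nrf2 -/- cells, 3 against 3 libraries make only 10 splits, too few for a share under 0.05. The real split gave 441, 4477, 7205 and 6292 genes for IFN-γ at 1, 8, 24 and 48 h, 2333 and 9368 for thapsigargin at 1 and 8 h and 9969 for time, and the highest other split gave 0 in each; the real split was thus 1 of 10 each time.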

How the results depend on the processing

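Requiring an absolute log2 fold of at least 1 cut every treatment and time count by over 1.5 times. The other settings moved these counts by as much only for thapsigargin at 1 h with libraries of the same time, and leaving out 1 library did so for IFN-γ in wild type at 1 and 48 h and for thapsigargin at 1 h. The genotype counts depended on the tool and on single libraries; the cause was not tested. At 32.3 to 54.7 M counts per library, genes with few counts in the control groups limited the folds that could be given. No paired analysis was possible because the replicate numbers only follow the order of the records and no label links libraries of the same culture. That reason concerns the labels only. Within each hour the high-Xist Nrf2 -/- libraries had the same numbers in every treatment. The wild-type score over genes linked to Nfe2l2 repeated by number at 1 h (1.60, 1.58 and 1.54 against 0.62, 0.65 and 0.63). It did at 24 h (0.64 and 0.62 against 1.55 and 1.60). At 48 h it did not (0.97 and 1.58 against 1.03 and 0.63). At 8 h replicate 1 scored 0.45, 0.79 and 0.49, and treated replicate 2 scored 1.26 and 2.02. Wild-type Xist repeated by number at 1 h (3.72, 4.77 and 2.8 against 0.35, 0.5 and 0.4 CPM). It did so at 48 h (4.26 and 3.11 against 0.34 and 0.43) but not 24 h (0.12 and 3.98 against 4.18 and 2.19). At 8 h it was mixed (untreated 2.9 against 2.66, IFN-γ 0.39 against 3.12). The values thus point to linked libraries at 1 h and are mixed later, and no model with such pairs was fitted. All treatment responses and their differences between genotypes rest on an unpaired model. The DESeq2 Wald test called 14 genes for the genotype in untreated cells, 53 with IFN-γ and 170 with thapsigargin, and 1, 2, 13 and 5 genes for the IFN-γ differences between responses at 1, 8, 24 and 48 h, 1 and 2 for thapsigargin and 14 for time. An added absolute log2 fold of at least 1 left 2, 3 and 3 genes for the genotype, 166, 1463, 2540 and 2139 for IFN-γ in wild type, 151, 1528, 2440 and 2099 in Nrf2 -/-, 142 and 3576 for thapsigargin in wild type, 133 and 3610 in Nrf2 -/-, and 3521 and 3825 for time. With no low-count filter the genotype count with IFN-γ was 18. With only the libraries of the same time or treatment it was 5 with IFN-γ and 44 with thapsigargin, and thapsigargin at 1 h gave 2709 in wild type and 2333 in Nrf2 -/-, with 1 gene for the IFN-γ and 12 for the thapsigargin difference at 1 h. The term for high Xist left 3 genes for the genotype with thapsigargin. Leaving out the 3 libraries with conflicting labels left 4 there, and counting them as wild type gave 1 untreated, 5 with IFN-γ and 0 with thapsigargin. Leaving out the 2 doubted untreated 8 h libraries gave 16 for the genotype with IFN-γ, and kallisto estimated counts gave 9 for untreated cells. Leaving out 1 library at a time gave 3 to 7 genes for the genotype untreated, 8 to 121 with IFN-γ and 2 to 118 with thapsigargin; ranges for IFN-γ in wild type were 197 to 258, 3173 to 3632, 5793 to 6594 and 4720 to 7220, in Nrf2 -/- 250 to 312, 4386 to 4658, 6998 to 7410 and 6601 to 7080, for thapsigargin 674 to 969 and 7561 to 8630 in wild type and 992 to 1294 and 9176 to 9392 in Nrf2 -/-, and for time 7635 to 8294 and 9472 to 9633. For differences between responses they were 0 to 0, 0 to 1, 0 to 40 and 0 to 770 for IFN-γ, 0 to 0 and 0 to 201 for thapsigargin and 0 to 7 for time. A group left with 1 library was assumed to vary like the other groups. With the Xist term the camera direction of a list turned for sex-linked transcripts in untreated cells (median 0.03, camera adjusted p = 0.187). It also turned with IFN-γ for sex-linked transcripts (−0.01, 0.692) and cholesterol synthesis (0.02, 0.242). The same term weakened the untreated genotype calls for myelin (0.01, 0.532), cell cycle (0.05, 0.106) and progenitor (0.04, 0.239), myelin with IFN-γ (−0.01, 0.153), ER chaperones with thapsigargin (−0.03, 0.213), endothelial markers in Nrf2 -/- IFN-γ at 1 h (0.27, 0.0503) and immediate early genes in Nrf2 -/- thapsigargin at 8 h (1.03, 0.0531), and strengthened type I interferon-stimulated genes with IFN-γ (−0.09, 0.00614) and cholesterol synthesis with thapsigargin (0.05, 0.0206). Without the 3 conflicting libraries weaker values were MHC class I 0.07 (0.0680) for the genotype untreated, cholesterol −0.03 (0.0567) with IFN-γ, ATF4 −0.12 (0.0528) and glutathione −0.13 (0.0528) for the IFN-γ 24 h difference and ER chaperones 0.10 (0.0838) for the thapsigargin 8 h difference. Without the 2 doubted libraries they were cholesterol −0.04 (0.0566) with IFN-γ, ER chaperones −0.04 (0.0576) with thapsigargin, endothelial markers 0.29 (0.128) in wild-type IFN-γ at 8 h and −0.01 (0.0787) in Nrf2 -/- IFN-γ at 1 h, ATF4 0.13 (0.0694), ER chaperones 0.09 (0.0694) and cell cycle 0.12 (0.30) for the thapsigargin 8 h difference, with NF-κB genes in Nrf2 -/- IFN-γ at 48 h stronger at 1.68 (0.0445). DESeq2 size factors weakened ATF4 (−0.11, 0.0518) and glutathione (−0.12, 0.0518) in the IFN-γ 24 h difference and ATF4 (0.13, 0.0527) in the thapsigargin 8 h difference. Of 742 named gene and comparison pairs 448 passed the threshold, 40 of these fell short under some alternative and 42 when some library was left out.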

Other observations

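Some genes outside the usual IFN-γ programme changed strongly in both genotypes. Car2, the carbonic anhydrase of mature oligodendrocytes, rose at 8 h (5.46 ± 0.28 SE in wild type, 4.89 ± 0.22 in Nrf2 -/-) and at 24 h (3.47 ± 0.26 and 3.57 ± 0.22) while 15 and 17 of 28 myelin genes fell at 8 h and 22 in each genotype at 24 h. Tubb3, a tubulin of neurons, rose at 8 h (2.48 ± 0.13 and 2.43 ± 0.10) together with Sox11 (2.03 ± 0.12 and 1.72 ± 0.09), and the early growth gene Egr2 rose at 1 h (2.65 ± 0.26 and 2.33 ± 0.21) and stayed high at 8 h. The smooth-muscle actin gene Acta2 rose in wild type at 24 h (5.08 ± 0.41). The G-protein subunit gene Gng4 (−4.36 ± 0.22 and −4.50 ± 0.18) and Elmod1 (−4.31 ± 0.23 and −4.34 ± 0.19) fell steeply at 24 h in both genotypes. At 48 h the transcription factor Maf (−4.44 ± 0.38 and −4.28 ± 0.32) and the protocadherin Pcdh8 (−4.03 ± 0.21 and −3.66 ± 0.17) fell in both. Arc, a neuronal activity gene, rose over time in untreated cells (8.75 ± 0.38 and 7.01 ± 0.27) and was lower after 48 h of IFN-γ (−2.65 ± 0.23 and −2.88 ± 0.20). All of these passed the edgeR threshold.

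Nfe2l2 itself followed maturation in wild-type cells, from 7.98 ± 1.02 CPM at 1 h to 67.6 ± 3.96 CPM at 48 h in untreated cells, and IFN-γ held it to 34.2 ± 5.80 CPM at 48 h. NRF2 targets did not follow as a list over time (12 of 30 rose and 9 fell in wild type, median 0.25, camera BH-adjusted p = 0.828; 12 rose and 8 fell in Nrf2 -/-, median 0.26).

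Each Nrf2 -/- group contains 2 libraries high in Xist and 1 low, and the low-Xist libraries of different groups deviated from their group means together; this test was chosen after the Xist levels were seen and before its own value was. The mean pairwise correlation of residuals between the 10 low-Xist Nrf2 -/- libraries over 8948 autosomal genes was 0.09, against a mean of 0 and a highest value of 0.28 over 10000 random picks of 1 library per group (permutation p = 0.035). Autosomal expression tied to sex could give the same correlation, so whether the same cultures were sampled at several times and treatments stays open, and with it whether the libraries are independent. A record linking libraries to cultures would settle it.

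AY036118, a transcript that overlaps ribosomal RNA sequence, took 1.02% to 14.55% of counts, and mitochondrial transcripts 0.55% to 0.95%. No replicates of the same group were duplicates of each other (replicate chi-square per degree of freedom 5.47 to 373). Genes detected ranged from 16853 to 19819 per library.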
